A study of Mus musculus with 2 samples.

How the data were processed

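Bone marrow of 3 mice carrying Hoxa9/Meis1 leukaemia was pooled and captured in 1 droplet single-cell library with 3' counting of unique molecular identifiers (UMIs), per the labels' protocols. Cells of each mouse carried an antibody hashtag before pooling: hashtag 4 for the primary recipient, hashtag 5 for the secondary recipient of Lin- LSCs and hashtag 6 for the secondary recipient of Lym+ LSCs. Both are secondary recipients of that primary mouse. The labels give a target of 18000 cells, and the deposited tables hold 9616. The submitters' processing notes name Cell Ranger 3.1.0, STAR, Seurat 3.1.5 and 3.1, R 3.6.3 and the mouse genome build mm10, without saying which step each served.

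The deposited expression tables hold a scaled score per gene and cell, not counts. Tested on the values, each gene has a mean of 0 and an SD of 1 over all 9616 cells where no cell reaches the upper limit of 10, so the 3 tables were scaled together. The deposited metadata give per cell the count of RNA UMIs, of genes and of hashtag UMIs, a hashtag margin, S and G2M scores, a phase and a cluster number. All cells are marked as singlets there, and no doublet caller was run here. Doublets within 1 mouse cannot be seen by hashtag. A mitochondrial share and reads per hashtag were not used here.

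UMI counts were recovered from the scaled scores. For each gene, cells without a UMI lie on a plane in the S and G2M scores, and the distance of the other cells from that plane gives log(1 + 10000 × count / cell total) up to the gene's SD. With the deposited UMI total of each cell this gave counts for 10596 of 13459 genes, and 100% of their values below the limit were whole within 0.01. For 2856 genes every cell with a UMI was at the limit, so only detection is known and 1 UMI per cell was used; these genes were seen in at most 42 cells. A further 5 genes had 1 value in every cell and 2 mitochondrial genes could not be recovered. The recovered counts hold 98.5% of the deposited UMIs. Among recovered genes, 1.14% of values with a UMI were at the limit, where the count is a lower bound. On simulated data for the Lin- against primary comparison (3000 genes, 200 of them changed), 100% of values below the limit were recovered exactly. There, 97.9% of genes changed 0.25-fold and 95.8% of those changed 2-fold came within 0.3 of the true log2 fold, as did 100% of those changed 0.5-fold and 4-fold. Of 456 unchanged genes 0 passed 2-fold. Apart from the fold changes, these counts were drawn at 1 rate per gene over all cells and scaled by the formula that was then inverted. The simulation thus checks the inversion, not whether the deposited scores were made that way. It recovered 99.995% of UMIs, so it says little on genes confined to few cells, where many values lie at the limit. Before the data were examined it was set that counts would be used where they could be had, and mean scaled values otherwise.

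Counts were summed per mouse and scaled by the mouse's total UMIs to CPM. Ratios are log2 with 1 CPM added to both values, or 10 CPM within clusters. With 1 mouse per group no test is possible, and no p-value is given. Sums carry exact Poisson 95% intervals, shares carry exact Clopper-Pearson 95% intervals, and ratios carry exact conditional intervals. All of these cover counting error only, not variation between mice. As a floor set apart from these intervals, and lower than their upper bounds, a count of 0 was taken to allow up to 3 counts. Genes were named by a rule fixed beforehand: Hoxa9 and Meis1, the 10 highest and 10 lowest ratios per comparison among genes at 50 CPM or more in either mouse, the best-detected members of each gene list, and up to 5 leading genes per cluster. Unannotated models are given only as a number. For 31 gene lists also fixed then, members with a mean of at least 10 CPM were used, and members at least 1.5-fold apart were counted. Where at least 3 members remained, the list median was placed among the medians of 10000 random lists matched on mean expression in 20 bins. To compare detection and phases across depths, each cell was thinned to 500 UMIs; no cell was shallower. Thinned phases used the fixed S and G2M lists, centred over all cells.

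The authors' clusters were used. A cluster was named only where at least 3 list genes stood among its 50 leading genes, 1 list had the most, and no other list had more among the 10 leading genes. Leading genes had a UMI in at least 10% of the cluster's cells and at least 50 CPM there. Alternatives used clusterings of the recovered counts with 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolutions 0.3 and 1. Added after seeing the data were a clustering at resolution 0.5 and clusterings at resolutions 0.3, 0.5 and 1 that left out 76 genes differing at least 2-fold between mice. A new cluster was the counterpart of the authors' cluster from which most of its cells came. Also added after seeing the data were composition held fixed over clusters with at least 50 cells of each mouse, leaving out the 3 rarest clusters, leaving out the cell with the most Ighm UMIs, adding Mzb1 to the rare B-lineage genes, and a limit of 2% of cells for these genes in place of 1%. Alternatives set beforehand were cells with at least 1000 genes, cells up to the 98th percentile of UMIs, detection in place of CPM (at least 5% of cells in either mouse), no CPM minimum, a minimum of 200 CPM, a prior of 10 CPM and the largest cluster alone. Gene coordinates are from GENCODE M21 on mm10, in which 13315 of the 13459 symbols were found. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.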

Results

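The data are single-cell transcriptomes of bone marrow from 3 mice of a leukaemia model driven by Hoxa9 and Meis1, a homeobox transcription factor and its cofactor. There was 1 mouse per condition, so no difference below has a replicate check. The primary recipient gave 3088 cells, the secondary recipient of Lin- LSCs 3575 and the secondary recipient of Lym+ LSCs 2953. They held 6534561, 10011104 and 6681890 UMIs. The median cell had 1845 UMIs and 852 genes in the primary recipient, 2580 UMIs and 1064 genes in the Lin- recipient, and 2050 UMIs and 868 genes in the Lym+ recipient. Median hashtag UMIs per cell were 491, 540 and 246 in the same order. By the floor of 3 counts, a count of 0 allows up to 0.0972%, 0.0839% and 0.102% of cells with a UMI, which does not limit the share of cells expressing a gene.

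Hoxa9 (mm10 chromosome 6, 52223100 to 52231089) and Meis1 (chromosome 11, 18879817 to 19018985) were low in all mice. Hoxa9 stood at 26.3 CPM (95% interval 22.5 to 30.6) in the primary recipient, 22.4 CPM (19.5 to 25.5) in the Lin- recipient and 26.9 CPM (23.1 to 31.2) in the Lym+ recipient. Meis1 stood at 13.6 CPM (10.9 to 16.8), 9.79 CPM (7.95 to 11.9) and 14.1 CPM (11.4 to 17.2). The intervals of the Hoxa9 ratios held 0 in all 3 comparisons. Those of Meis1 excluded 0 where the Lin- recipient was compared, at a log2 ratio of -0.44 (-0.91 to -0.046) against the primary and of 0.48 (0.099 to 0.95) for Lym+ against Lin-, and held 0 for Lym+ against primary. At 500 UMIs per cell Meis1 was seen in 0.680% (0.421 to 1.04) of primary, 0.420% (0.235 to 0.691) of Lin- and 0.610% (0.362 to 0.962) of Lym+ cells, with overlapping intervals, and unthinned in 2.75%, 2.60% and 3.12%. The Lin- share stayed lowest, but thinning leaves too few cells with a UMI for the overlap to decide on the difference. In cells of cluster 0 alone its log2 ratio of Lym+ against Lin- was 0.016. The labels do not say whether transcripts of the introduced genes can be counted at the 3' end.

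The series title names a pro-B population, so B-lineage transcripts were examined in each mouse. The B-cell receptor component Cd79a had a UMI in 0.0648%, 0.0839% and 0.135% of cells of the primary, Lin- and Lym+ recipients. The B-lineage transcription factor Ebf1 had one in 0.0972%, 0.0559% and 0.0677%, and the surrogate light chain gene Vpreb1 in 0.583%, 0.531% and 0.271%. These are 2 to 4 cells per mouse for Cd79a and Ebf1. Cd79b, the partner of Cd79a, was seen more widely, in 2.04% (1.57 to 2.6), 1.37% (1.02 to 1.81) and 1.12% (0.77 to 1.57) of cells, at 9.64, 5.09 and 5.09 CPM. Against the primary its log2 ratio was -0.80 (-1.48 to -0.36) in the Lin- and -0.81 (-1.57 to -0.30) in the Lym+ recipient, with 8, 2 and 7 cells at the upper limit of the scaled values. At 500 UMIs per cell its shares were 0.259%, 0.252% and 0.169%, with overlapping intervals and too few cells to decide. It was seen in 2.86% (2.18 to 3.68) of cluster 0, at a median of 2943 UMIs, and in 0.248% (0.03 to 0.891) of cluster 4, at 982.5 UMIs. Of the 19 genes of the pro-B list 12 had deposited values. Among these 1 reached a mean of 10 CPM, the surface receptor Cd93, at 114.9, 109.3 and 110.6 CPM. Of the 15 genes of the immunoglobulin and V(D)J recombination list 10 had values, and 1, Ighm, reached it. The other genes of both lists were absent from the deposited expression values, so they cannot be called low. Cells with UMIs of at least 2 of 21 rare B-lineage genes, those seen in at most 1% of all cells, made up 0.291% (0.133 to 0.553) of the primary, 0.28% (0.134 to 0.514) of the Lin- and 0.169% (0.055 to 0.395) of the Lym+ recipient. These intervals overlap. Mzb1, a protein of the endoplasmic reticulum and a member of the plasma cell list, was above that limit, as was Cd79b, and is given apart, a choice made after its values were seen. It was higher in the Lym+ recipient, at 20.1 CPM (16.8 to 23.8) against 4.44 CPM (2.97 to 6.37) in the primary and 3.8 CPM (2.69 to 5.21) in the Lin- recipient, and had a UMI in 3.59%, 0.745% and 0.839% of cells in that order. Its value lay at the upper limit of the scaled values in 11, 5 and 3 of these cells, so the CPM are lower bounds. At 500 UMIs per cell the shares were 1.05% (0.714 to 1.49), 0.227% (0.0912 to 0.466) and 0.196% (0.0788 to 0.403). It was seen in 3.99% (3.07 to 5.09) of cluster 2, at a median of 1488 UMIs, and in 0.371% (0.0766 to 1.08) of cluster 4, at 982.5 UMIs. Cluster 2 was led by Cpa3, Cox6a2 and Clec10a, and held 19.5% of primary and 19.7% of Lym+ cells. The Mzb1 shares per cluster pool the 3 mice, so they do not show where the higher Mzb1 of the Lym+ recipient lay. Whether it is a B-lineage signal is left open. With a limit of 2% of all cells, which adds Cd79b and Mzb1, 0.421% of primary, 0.476% of Lin- and 0.373% of Lym+ cells held at least 2 of the genes. Ighm, the immunoglobulin mu heavy chain (chromosome 12, 113418558 to 113422730), was detected far more widely, in 25.8%, 28.1% and 28.6% of cells. At 500 UMIs per cell the shares were 8.58%, 7.24% and 9.08%. By cluster its share ran from 5.45% (3.98 to 7.24) in cluster 4, with a median of 982.5 UMIs per cell, to 37.7% (35.3 to 40.1) in cluster 2, with a median of 1488 UMIs. Its level was 157.6 CPM in the primary, 134.4 CPM in the Lin- and 295.7 CPM in the Lym+ recipient. A single Lym+ cell held 894 of the 1976 Ighm UMIs of its mouse, and without it the Lym+ value was 162 CPM. UMIs of at least 2 of 10 rare T or NK genes were seen in 0.421% (0.224 to 0.719), 0.14% (0.0454 to 0.326) and 0.135% (0.0369 to 0.346) of cells.

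The authors divided the cells into 11 clusters. Cluster 8 was granulocyte-monocyte progenitor-like, with 6 list genes among its 50 leading genes, among them the granule protease Elane and the granule protein gene Nkg7. Every other cluster stayed unnamed under the naming rule. Cluster 10 was led by the neutrophil genes S100a9, S100a8, Camp and Ngp, and cluster 9 by the MHC class II genes Cd74, H2-Aa and H2-Eb1. Cluster 1 was led by Ccl3, 1 unannotated model and Snx14. In cluster 5 the first leading gene was 1 unannotated model, at 4264 CPM against 426.6 CPM in other cells. Ighm, Sun2, P4hb and Rab44 came next there. The cell with the most Ighm UMIs lay in cluster 5, where Ighm stood at 1201 CPM and ranked second by ratio; without it Ighm stood at 221.7 CPM and ranked 613. Clusters 3 and 7 were led by histone and mitotic genes such as Hist1h2ap and Cenpf.

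Shares of cells were compared for clusters that had a counterpart when the cells were clustered anew without the genes differing between the mice, at resolution 0.3, 0.5 or 1. Cluster 7 had no counterpart in any new clustering, with or without those genes, so its share is drawn in the plot of cluster shares but not compared. Clusters 1, 5, 8, 9 and 10 had shares at least 2-fold apart in some pair of mice; both rules were set after the shares were seen. The progenitor-like cluster 8 held 9.07% (8.08 to 10.1) of primary cells, 0.699% (0.453 to 1.03) of Lin- cells and 1.12% (0.770 to 1.57) of Lym+ cells. Its counterpart at resolution 1 with all genes took in 76% of its cells and held 10.5%, 1.57% and 1.39%. Without the differing genes it had a counterpart at resolution 1 alone, which took in 38.8% of its cells and held 4.37%, 0.448% and 0.880%. Cluster 1 held 24.2% (22.6 to 25.8) of Lym+ cells, 11.2% (10.1 to 12.3) of primary cells and 15.9% (14.8 to 17.2) of Lin- cells, and its counterpart without the differing genes, also at resolution 1 alone, held 25.2%, 12.3% and 12.3%. Cluster 9 held 4.03% (3.35 to 4.80) of Lym+ cells, 0.486% (0.272 to 0.8) of primary cells and 0.727% (0.476 to 1.06) of Lin- cells; its counterpart at resolution 0.5 without the differing genes held 5.42%, 1.46% and 1.23%. Cluster 10 held 3.11% (2.53 to 3.78) of primary cells, 0.531% (0.320 to 0.829) of Lin- cells and 0.271% (0.117 to 0.533) of Lym+ cells, and its counterpart of the same kind held 2.27%, 0.476% and 0.237%. Cluster 5 held 3.25% (2.64 to 3.96) of Lym+ cells, 8.97% (7.99 to 10.0) of primary cells and 8.11% (7.24 to 9.06) of Lin- cells, and its counterpart held 2.81%, 9.13% and 7.89%.

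The differences in points changed with the depth of the cells kept. In cells with at least 1000 genes, cluster 9 differed by 0.749 percentage points between the Lym+ and the primary recipient, against 3.54 in all cells, and by 0.685 between the Lym+ and the Lin- recipient, against 3.30. Cluster 5 was 1.17 points lower in the Lym+ than in the primary recipient in such cells, against 5.72 in all, and 2.66 points lower than in the Lin- recipient, against 4.86. Cluster 10 was 1.08 points higher in the primary than in the Lin- recipient, against 2.58, and 1.29 points higher than in the Lym+ recipient, against 2.84. For cluster 8 the differences were larger in such cells, at 14.6 points against 8.37 between the primary and the Lin- recipient and 13.5 against 7.95 between the primary and the Lym+ recipient. Clusters 5 and 9 had medians of 1125 and 924.5 UMIs per cell and cluster 8 had 2770. Median genes per cell were 654, 490 and 730 in clusters 5, 9 and 10, so the limit of 1000 genes drops most of their cells. Smaller differences in points follow from that and do not show that depth made the differences in all cells. Cluster 8 had a median of 1153.5 genes.

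**Figure D1:**
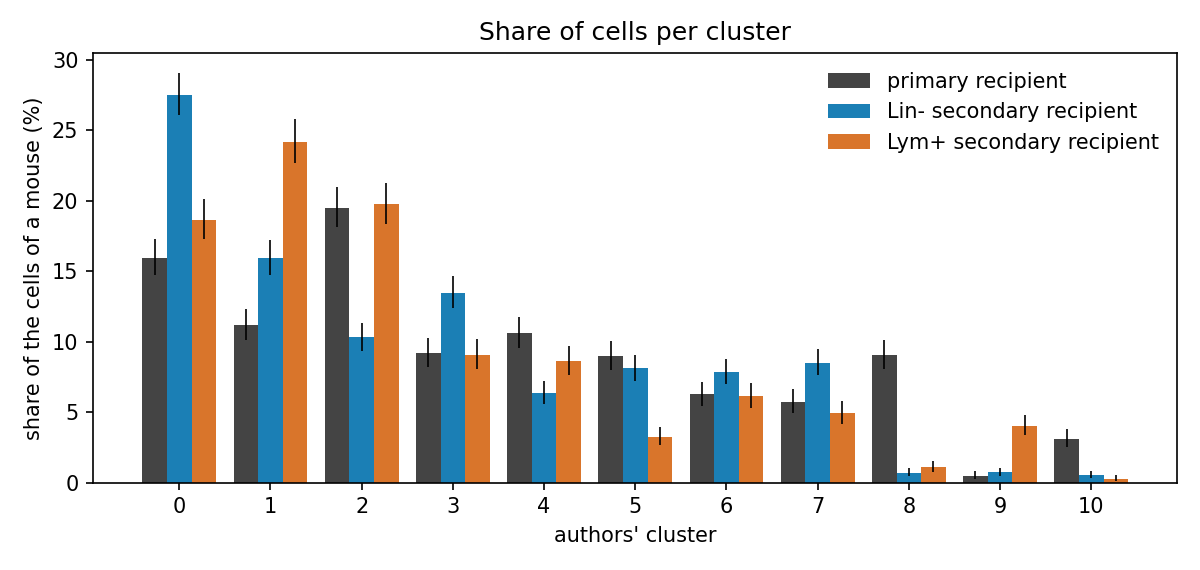
Share of the cells of each mouse (y axis, %) in each of the authors' clusters (x axis). Bars are the 3 mice and lines are exact 95% intervals that cover counting error only. Cluster 9 stands at 4.03% in the Lym+ recipient against 0.486% in the primary. Cluster 8 stands at 9.07% in the primary against 0.699% in the Lin- recipient. Cluster 7 is drawn but not compared.

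The Lin- recipient against the primary recipient sets the marrow of a mouse given Lin- LSCs beside that of the primary recipient. Immediate early genes, which cells switch on within minutes of a stimulus, were lower in the Lin- recipient. Of 11 genes of the immediate early and heat shock list, 10 were at least 1.5-fold lower and 0 higher, with a median log2 ratio of -1.50, below all of the 10000 random lists. The other was the heat shock gene Hsp90aa1, at 494.5 CPM against 490.9 CPM. The heat shock genes Hspa1a and Hspa1b of the same list, named after their values were seen, had a mean under 10 CPM and were not counted. Both were lower, at 0.599 CPM (0.22 to 1.3) against 23.9 CPM (20.3 to 27.9) and at 0.699 CPM (0.281 to 1.44) against 21.3 CPM (17.9 to 25.1). These are near-identical copies, so the split between them is uncertain, and 19 and 20 primary cells lay at the upper limit of the scaled values, so the primary values are lower bounds. Fos stood at 55.9 CPM (51.4 to 60.8) against 299.8 CPM (287 to 313), Jun at 82.5 CPM (77 to 88.3) against 340.3 CPM (326 to 355), and Dusp1, a phosphatase that acts on MAP kinases, at 10.4 CPM (8.49 to 12.6) against 79.4 CPM (72.7 to 86.6). Fos, Jun and Dusp1 were lower in all 8 clusters that held at least 50 cells of each mouse.

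Granulocyte genes were lower as well, and so was the share of the progenitor-like cluster 8, at 0.699% of cells against 9.07%. Of 9 neutrophil precursor genes 8 were at least 1.5-fold lower (median log2 -1.09), as were 5 of 8 mature neutrophil genes (median -0.69) and 6 of 10 secondary and tertiary granule genes (median -0.86). Camp, a cathelicidin, stood at 221.4 CPM against 1291 CPM and S100a8, a calcium-binding alarmin, at 531.5 CPM against 2223 CPM. S100a8 was seen in 100% of cluster 10, where the median depth was 1906 UMIs, in 0.625% (0.0158 to 3.43) of cluster 9, at 924.5 UMIs, and in 1.73% (1.2 to 2.39) of cluster 0, at 2943 UMIs. Over the 8 clusters with at least 50 cells of each mouse, which leave out clusters 8, 9 and 10, and with their composition held fixed, the mature neutrophil median was 0.12 and the log2 ratio of S100a8 was 0.015. The transcription factor Cebpe was lower, at 11.4 CPM (9.39 to 13.7) against 98.9 CPM (91.4 to 107), and so was Cd63, a granule membrane protein, at 45.9 CPM against 278.2 CPM; both were lower in all 8 clusters. Of 5 basophil, eosinophil or mast cell genes 4 were lower (median -1.60), among them the carboxypeptidase Cpa3 at 41.1 CPM against 271.9 CPM. The other, Mcpt8, stood higher, at 27.4 CPM against 20.2 CPM. Of the 4, Cpa3 led cluster 2 (640.3 CPM against 57.4 CPM in other cells), Ccl3 led cluster 1, and Prg3 was among the leading genes of cluster 8. Ccl3 is also in the inflammatory list and Gata2 in the stem and progenitor list, so the 4 are not read as a single lineage. Of 15 myeloid transcription factors 6 were lower (median -0.44), Fos and Jun of the immediate early list among them, as were 2 of 11 granulocyte-monocyte progenitor genes (median -0.18), 2 of 9 primary granule genes (median -0.19), 2 of 9 stem and progenitor genes (median -0.27), 2 of 3 inflammatory genes (median -0.97) and 1 of 5 interferon response genes (median -0.32). Of 6 MHC class II genes 0 were 1.5-fold apart (median 0.26, or 0.063 without the 3 rarest clusters and 0.46 in cells with at least 1000 genes). With composition held fixed over the same 8 clusters, and so without the progenitor-like cluster 8, the progenitor and primary granule medians were 0.013 and 0.0042, the neutrophil precursor median was -0.35, the secondary and tertiary granule median -0.25 and the interferon response median -0.19. Without the 3 rarest clusters the progenitor median was 0.11, the primary granule median -0.062, the neutrophil precursor median -0.53 and the secondary and tertiary granule median -0.34. In cells with at least 1000 genes the medians were -0.23 for mature neutrophil genes, -0.25 for myeloid transcription factors, -0.17 for stem and progenitor genes and -0.10 for interferon response genes, and in cells thinned to 500 UMIs they were -0.067 for progenitor and -0.12 for primary granule genes.

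Other genes were higher. The creatine kinase Ckm stood at 112.5 CPM (106 to 119) against 33.4 CPM (29.1 to 38.1), the cold-inducible RNA-binding protein gene Cirbp at 241.7 CPM against 115.8 CPM and Phka2 at 85.3 CPM against 41.3 CPM, each higher in all 8 clusters. The myeloperoxidase gene Mpo was at 1818 CPM against 1274 CPM, and at 500 UMIs per cell it was seen in 38.6% (37 to 40.2) against 23.1% (21.6 to 24.7) of cells, or in 61.8% against 39.2% unthinned. Of 20 S phase and 19 G2 and M phase genes, 0 were 1.5-fold apart, though their medians, 0.15 and 0.28, lay above 99.97% and 100% of random lists. In cells with at least 1000 genes these medians were -0.093 and 0.027, and in cells thinned to 500 UMIs the S phase median was 0.29. Thinned phase calls placed 33% of Lin- and 45.5% of primary cells in G1, against 36.9% and 52.9% in the deposited calls. Over all genes at 50 CPM or more, 3 of 2541 had a ratio of at least 2 and 30 a ratio of 0.5 or less; these are counts by size, not by a test. By share of cells with a UMI, unthinned, 37 genes were at least 2-fold higher and 17 lower.

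**Figure D2:**
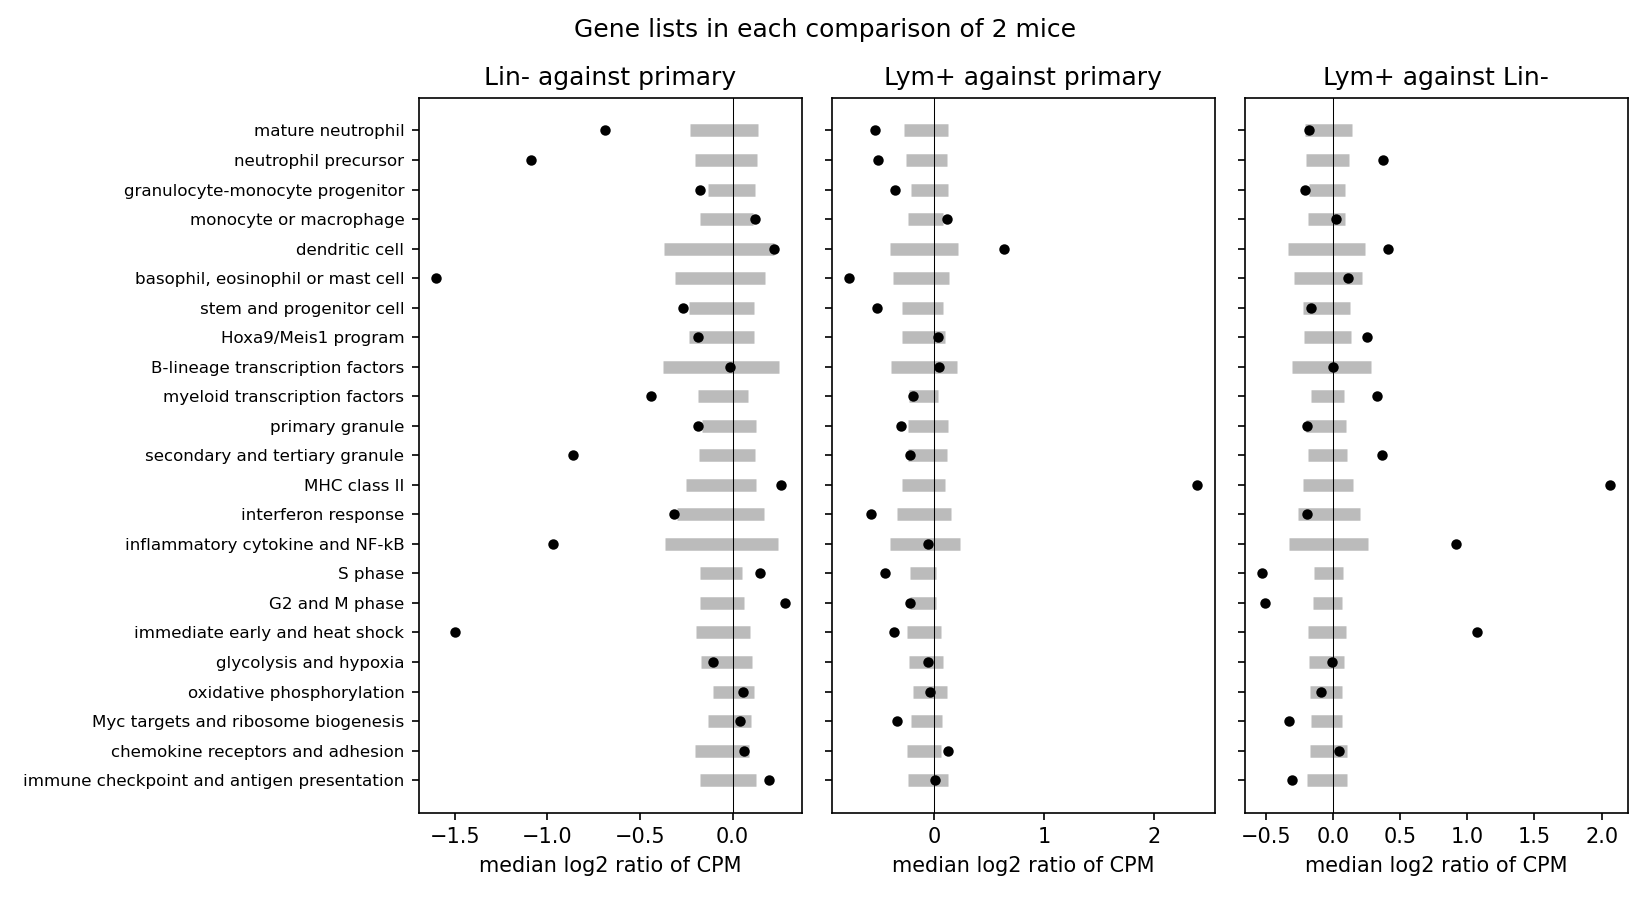
Median log2 ratio of CPM (x axis) of each gene list (y axis) in the 3 comparisons of 2 mice. Points are list medians and grey bars hold the middle 95% of 10000 random lists matched on expression. The immediate early list lies at -1.50 in Lin- against primary, and MHC class II at 2.39 in Lym+ against primary.

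The Lym+ recipient against the primary recipient does the same for the mouse given Lym+ LSCs. MHC class II genes, which present antigen to T cells, were higher: 4 of 6 were at least 1.5-fold higher, with a median log2 ratio of 2.39. H2-Eb1 stood at 97.7 CPM (90.4 to 106) against 11.2 CPM (8.76 to 14), H2-Aa at 103.6 CPM (96 to 112) against 13.5 CPM (10.8 to 16.6) and Cd74, the invariant chain, at 308.1 CPM (295 to 322) against 43.2 CPM (38.3 to 48.5). Cluster 9 held 98% of the H2-Eb1, 97.1% of the H2-Aa and 95.8% of the Cd74 UMIs of the Lym+ recipient. With composition held fixed over the 8 clusters, which leave out clusters 8, 9 and 10, the list median was 0.76. Without the 3 rarest clusters it was 0.56 and in cells with at least 1000 genes 1.5. These values include H2-Aa and H2-Eb1, which outside cluster 9 stood at 3.05 CPM against 0.614 CPM and 1.99 CPM against 0.614 CPM. Over the 4 members that reached 10 CPM in at least 1 mouse outside cluster 9 the median was 0.34. Cd74 reached it only in the Lym+ recipient, at 13.3 CPM against 6.90 CPM. The others, H2-Ab1, H2-DMa and H2-DMb1, had log2 ratios of 0.35, 0.29 and 0.34. Within the 8 clusters the list medians ran from -0.014 to 1.03, with a middle of 0.21 and 1 of 8 lower. Of 3 dendritic cell genes 2 were higher (median 0.63), namely Flt3 and Cox6a2. Flt3 is also in the Hoxa9/Meis1 program list, and Cox6a2 led cluster 2 (160.5 CPM against 10.8 CPM in other cells). The 2 are therefore not read as a dendritic signature. Among the 50 leading genes of cluster 9 stood 2 of the dendritic list, short of the 3 needed for a name. Dennd5b at 301.1 CPM against 122.9 CPM, Tsc22d3, a glucocorticoid-induced gene, at 210.3 CPM against 90.6 CPM, and Phka2 at 113.1 CPM against 41.3 CPM were higher in all 8 clusters. Slc31a2 and Ckm were also among the 10 highest ratios.

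Neutrophil genes were lower here too. Ngp stood at 99.1 CPM against 1053 CPM, Camp at 141.4 CPM against 1291 CPM, S100a8 at 334.9 CPM against 2223 CPM and S100a9 at 312.5 CPM against 2015 CPM. Of 9 neutrophil precursor genes 4 were lower (median -0.51), and of 8 mature neutrophil genes 4 were lower and 1 higher (median -0.53). With composition held fixed over these 8 clusters, Camp and S100a8 had log2 ratios of 0.40 and 0.51 and the mature neutrophil median was 0.45, while the neutrophil precursor median was -0.054. In these clusters Camp stood at no more than 16.7 CPM in either mouse, and the interval of its ratio held 0 in each. S100a8 was lower in 5 of the 8, and in cluster 4 it stood at 341.5 CPM against 68.7 CPM. The 2 ratios are therefore not read as a rise across clusters. In cells with at least 1000 genes the mature neutrophil and neutrophil precursor medians were -0.14 and -0.25. Stfa1 and BC100530 were also among the 10 lowest ratios, but 35 of 67 primary cells with a Stfa1 UMI and 34 of 63 with a BC100530 UMI lay at the upper limit of the scaled values, so their primary counts are lower bounds. Cebpe was at 15.7 CPM against 98.9 CPM and the histidine decarboxylase gene Hdc at 12.6 CPM (10 to 15.6) against 59.8 CPM (54.1 to 66.1). Of 9 stem and progenitor genes 3 were lower (median -0.52), of 20 S phase genes 4 (median -0.44), of 5 interferon response genes 2 (median -0.58), of 11 immediate early and heat shock genes 3 (median -0.37; below the minimum for the count, Hspa1a and Hspa1b stood at 5.09 CPM against 23.9 CPM and at 3.44 CPM against 21.3 CPM), of 5 basophil, eosinophil or mast cell genes 3 (median -0.77) and of 11 granulocyte-monocyte progenitor genes 3 (median -0.36, or -0.13 with composition held fixed and -0.075 without the 3 rarest clusters). Of 9 primary granule genes 2 were lower (median -0.30, or -0.15 with composition held fixed). The Myc and ribosome biogenesis median was -0.34 with 0 of 15 genes 1.5-fold apart, and the G2 and M phase median -0.22 with 0 of 19, or -0.070 with composition held fixed and -0.12 in cells with at least 1000 genes. The median over all genes was -0.11, which small list medians stand against. By size, 12 of 2538 genes had a ratio of at least 2 and 19 of 0.5 or less.

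The Lym+ recipient against the Lin- recipient sets the marrow of the 2 secondary recipients side by side, 1 mouse for each transplanted fraction. A difference between the fractions cannot be told apart there from a difference between the mice. Immediate early genes were higher in the Lym+ recipient, as 10 of 11 genes of the immediate early and heat shock list were higher by at least 1.5-fold (median log2 1.07). The heat shock gene Hsp90aa1 was the exception, at 361.6 CPM (347 to 376) against 494.5 CPM (481 to 508). Hspa1a and Hspa1b, under the minimum for the count, were higher, at 5.09 CPM (3.52 to 7.11) against 0.599 CPM (0.22 to 1.3) and at 3.44 CPM (2.18 to 5.16) against 0.699 CPM (0.281 to 1.44), with 4 and 2 Lym+ cells at the upper limit of the scaled values. Fosb stood at 57 CPM (51.4 to 63) against 16 CPM (13.6 to 18.7), Jun at 272.1 CPM against 82.5 CPM, Fos at 182.7 CPM against 55.9 CPM and Jund at 197.7 CPM against 74.3 CPM, each higher in all 8 clusters. MHC class II genes were higher (4 of 6, median 2.06, or 0.53 with composition held fixed without clusters 8, 9 and 10 and 1.29 in cells with at least 1000 genes). Over the 4 members that reached 10 CPM in at least 1 mouse outside cluster 9, however, the median was 0.18. Cd74 reached it only in the Lym+ recipient, at 13.3 CPM against 4.61 CPM. The others, H2-Ab1, H2-DMa and H2-DMb1, had log2 ratios of -0.14, 0.066 and 0.30. Within the 8 clusters the list medians ran from -0.30 to 1.11, with a middle of 0.027 and 3 of 8 lower. Also higher were 4 of 15 myeloid transcription factors (median 0.33), namely Id2, Klf4 and again Jun and Fos, and 2 of 3 inflammatory genes (median 0.91). Of 3 dendritic cell genes 1, Cox6a2, was higher (median 0.41, or 0.27 with composition held fixed and 0.22 in cells with at least 1000 genes). Genes of the neutrophil lists went both ways. Of 9 neutrophil precursor genes 2 were higher and 2 lower (median 0.38, or 0.092 in cells thinned to 500 UMIs and 0.63 in cells with at least 1000 genes), and of 10 secondary and tertiary granule genes 4 were higher and 2 lower (median 0.37, or 0.60 in cells with at least 1000 genes), both medians above all random lists. Chil3 stood at 658.2 CPM against 392.1 CPM and Lcn2 at 173 CPM against 104.8 CPM. Ngp stood at 99.1 CPM against 192.6 CPM and Camp at 141.4 CPM against 221.4 CPM. These 4 genes are in both lists. Chil3 led cluster 6 (3868 CPM against 358.2 CPM in other cells), and Mmp8, also higher, was among the leading genes of cluster 4. Lcn2, Ngp and Camp were among the leading genes of cluster 10. S100a8 and S100a9, which also led cluster 10, were lower, at 334.9 CPM against 531.5 CPM and 312.5 CPM against 497.5 CPM. Fn1, fibronectin, was at 201.1 CPM against 74.5 CPM. Cell-cycle genes were lower: 7 of 20 S phase genes (median -0.53) and 3 of 19 G2 and M phase genes (median -0.50), among them the helicase subunit Mcm2 at 36.4 CPM (31.9 to 41.2) against 66.2 CPM (61.3 to 71.5) and Uhrf1 at 28.1 CPM against 50.8 CPM. In cells with at least 1000 genes the S phase and the G2 and M phase medians were -0.22 and -0.15, and in cells thinned to 500 UMIs the G2 and M phase median was -0.80. The Myc and ribosome biogenesis median was -0.33 with 0 of 15 genes 1.5-fold apart (-0.18 with composition held fixed, -0.17 in cells with at least 1000 genes), and 1 of 11 granulocyte-monocyte progenitor genes was lower (median -0.21, or -0.13 in cells with at least 1000 genes). Thinned phase calls placed 53.8% (52 to 55.6) of Lym+ and 33% (31.5 to 34.6) of Lin- cells in G1; the deposited calls gave 61.7% and 36.9%. Phase calls also read free RNA, so they are not taken as cycling. Spns1 at 112.5 CPM against 275.1 CPM and the class I gene H2-Q7 at 38.3 CPM against 93 CPM were lower in all 8 clusters, as was Mpo at 1001 CPM against 1818 CPM. H2-Q7 belongs to a family of near-identical genes, so its count is uncertain. By size, 19 of 2464 genes had a ratio of at least 2 and 4 of 0.5 or less, while by share of cells with a UMI, unthinned, 9 were at least 2-fold higher and 33 lower.

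**Figure D3:**
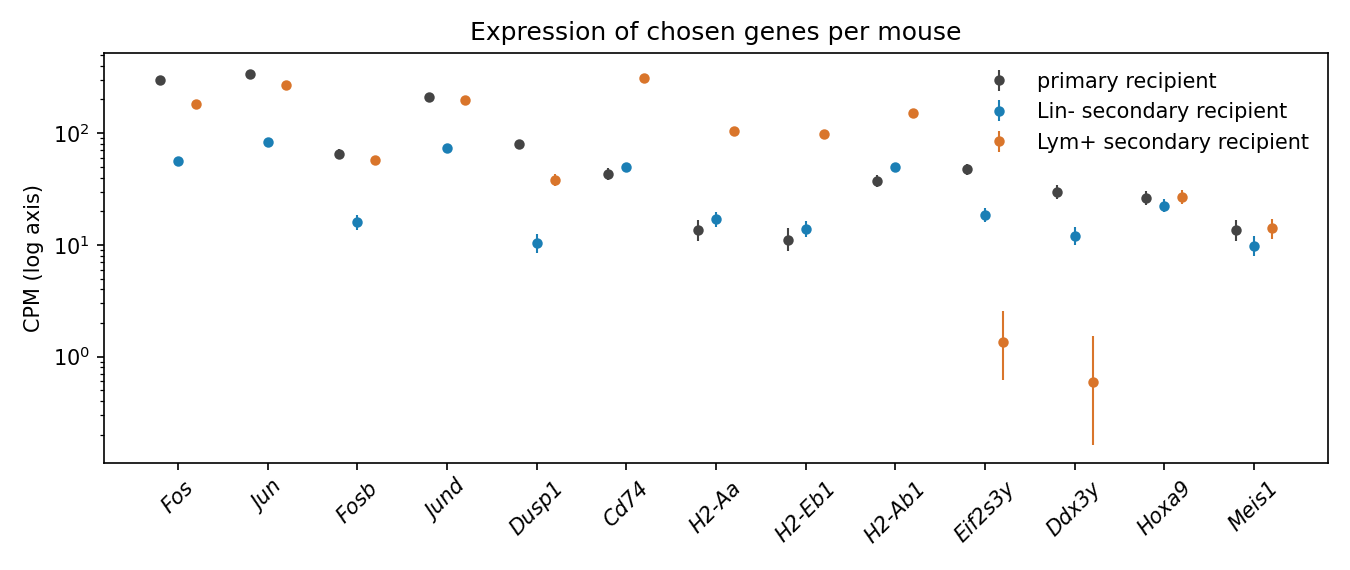
CPM (y axis, log scale) of genes named in the text (x axis) in the 3 mice; lines are exact Poisson 95% intervals. Fos stands at 55.9 CPM in the Lin- recipient against 299.8 CPM in the primary, and Hoxa9 between 22.4 and 26.9 CPM in all 3.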

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

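Composition held fixed, leaving out the 3 rarest clusters, leaving out the cell with the most Ighm UMIs, adding Mzb1 to the rare B-lineage genes or a limit of 2% of cells for them, own clusters at resolution 0.5 and all clusterings without differing genes were chosen after seeing the data; the others were set before. No paired analysis was possible because there was 1 mouse per group and no test. Some alternatives set before were not run: a mitochondrial share under 5% and an own-hashtag share of 90% need values not used here, and no cluster was named for lymphoid, erythroid or other non-myeloid cells. Clusters 1, 5 and 8 had no counterpart at resolution 0.3 with or without the differing genes, and clusters 1 and 8 none at resolution 0.5 without them, so they have no value there. Of 176 medians under these alternatives of lists outside the middle 95% of random lists, 118 moved by no more than 0.5 of the width of the random range, 46 moved further and 12 turned direction. Of 100 medians of lists inside it, 89 moved by no more than that and 11 further, and 28 of the 100 turned direction. Of named gene ratios 184 stayed in their counting interval, 168 left it and 21 turned. Of cluster share differences 32 stayed within their interval, 27 moved and 0 turned. Shares of cells with at least 2 rare B-lineage genes stayed within their intervals in both alternatives. Depth limits genes near the floor of 0.459, 0.3 and 0.449 CPM in the primary, Lin- and Lym+ recipients. The values that turned follow for named genes and for lists outside the middle 95% of random lists, with the values that moved for depth, cluster shares, counts of genes and these lists. Medians of lists inside it that moved or turned, and gene ratios that moved, are given here only as the counts above. The 200 CPM minimum tests fewer genes by construction, and other causes were not tested.

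In cells with at least 1000 genes, median UMIs per cell were 3116 (primary) and 3264.5 (Lym+). Likewise, in cells with at least 1000 genes, share differences in percentage points were 9.18 for cluster 1 (Lym+ minus primary), 1.17 for cluster 5 (primary minus Lym+), 2.66 for cluster 5 (Lin- minus Lym+), 14.6 for cluster 8 (primary minus Lin-), 13.5 for cluster 8 (primary minus Lym+), 0.749 for cluster 9 (Lym+ minus primary), 0.685 for cluster 9 (Lym+ minus Lin-), 1.08 for cluster 10 (primary minus Lin-) and 1.29 for cluster 10 (primary minus Lym+). Likewise, in cells with at least 1000 genes, genes at least 2-fold apart were 7 lower in Lym+ against Lin-. Likewise, in cells with at least 1000 genes, list medians of Lin- against primary were mature neutrophil -0.23, neutrophil precursor -0.87, myeloid transcription factors -0.25, secondary and tertiary granule -0.58, MHC class II 0.46, S phase -0.093, G2 and M phase 0.027 and immediate early and heat shock -1.26. Again in cells with at least 1000 genes, list medians of Lym+ against primary were mature neutrophil -0.14, neutrophil precursor -0.25 and MHC class II 1.5. Again in cells with at least 1000 genes, list medians of Lym+ against Lin- were neutrophil precursor 0.63, secondary and tertiary granule 0.60, MHC class II 1.29, S phase -0.22, G2 and M phase -0.15 and Myc targets and ribosome biogenesis -0.17. Again in cells with at least 1000 genes, log2 ratios of Lym+ against primary were Hoxa9 -0.18 and Meis1 -0.047. Again in cells with at least 1000 genes, log2 ratios of Lym+ against Lin- were Cd79b 0.19. Clustered at resolution 1 without differing genes, share differences in percentage points were 6.95 for cluster 5 (primary minus Lym+), 7.72 for cluster 5 (Lin- minus Lym+), 3.92 for cluster 8 (primary minus Lin-), 3.49 for cluster 8 (primary minus Lym+), 4.17 for cluster 9 (Lym+ minus Lin-), 1.89 for cluster 10 (primary minus Lin-) and 2.13 for cluster 10 (primary minus Lym+). In own clusters at resolution 1, share differences in percentage points were 7.25 for cluster 5 (Lin- minus Lym+) and 9.14 for cluster 8 (primary minus Lym+). In own clusters at resolution 0.5, share differences in percentage points were 6.83 for cluster 8 (primary minus Lin-). Clustered at resolution 0.3 without differing genes, share differences in percentage points were 4.15 for cluster 9 (Lym+ minus Lin-), 1.76 for cluster 10 (primary minus Lin-) and 1.997 for cluster 10 (primary minus Lym+). Clustered at resolution 0.5 without differing genes, share differences in percentage points were 4.19 for cluster 9 (Lym+ minus Lin-), 1.79 for cluster 10 (primary minus Lin-) and 2.03 for cluster 10 (primary minus Lym+). In own clusters at resolution 0.3, share differences in percentage points were 4.92 for cluster 10 (primary minus Lin-) and 4.99 for cluster 10 (primary minus Lym+). By share of cells with a UMI, genes at least 2-fold apart were 37 higher in Lin- against primary, 17 lower in Lin- against primary, 9 higher in Lym+ against Lin- and 33 lower in Lym+ against Lin-. Under no CPM minimum, genes at least 2-fold apart were 40 higher in Lin- against primary, 189 lower in Lin- against primary, 105 higher in Lym+ against primary, 169 lower in Lym+ against primary, 101 higher in Lym+ against Lin- and 64 lower in Lym+ against Lin-. Under the 200 CPM minimum, genes at least 2-fold apart were 1 higher in Lin- against primary, 11 lower in Lin- against primary, 3 higher in Lym+ against primary, 8 lower in Lym+ against primary, 6 higher in Lym+ against Lin- and 2 lower in Lym+ against Lin-. In cells of cluster 0 only, genes at least 2-fold apart were 11 higher in Lin- against primary, 18 lower in Lin- against primary and 11 lower in Lym+ against primary. Likewise, in cells of cluster 0 only, log2 ratios of Lin- against primary were S100a8 0.16. Likewise, in cells of cluster 0 only, log2 ratios of Lym+ against primary were H2-Eb1 -0.12, Cd74 -0.54, Hoxa9 -0.11 and Meis1 -0.54. Likewise, in cells of cluster 0 only, log2 ratios of Lym+ against Lin- were Cd74 -0.33 and H2-Ab1 -0.22. With cluster composition held fixed, genes at least 2-fold apart were 16 lower in Lin- against primary, 7 lower in Lym+ against primary and 10 higher in Lym+ against Lin-. Likewise, with cluster composition held fixed, list medians of Lin- against primary were mature neutrophil 0.12, neutrophil precursor -0.35, granulocyte-monocyte progenitor 0.013, primary granule 0.0042 and secondary and tertiary granule -0.25. Likewise, with cluster composition held fixed, list medians of Lym+ against primary were mature neutrophil 0.45, neutrophil precursor -0.054, granulocyte-monocyte progenitor -0.13, MHC class II 0.76 and G2 and M phase -0.070. Likewise, with cluster composition held fixed, list medians of Lym+ against Lin- were MHC class II 0.53, S phase -0.41, G2 and M phase -0.36, immediate early and heat shock 0.90 and Myc targets and ribosome biogenesis -0.18. Again with cluster composition held fixed, log2 ratios of Lin- against primary were S100a8 0.015. Again with cluster composition held fixed, log2 ratios of Lym+ against primary were Stfa1 0.12, Camp 0.40 and S100a8 0.51. Again with cluster composition held fixed, log2 ratios of Lym+ against Lin- were H2-Ab1 -0.16 and Cd79b 0.19. Without the 3 rarest clusters, genes at least 2-fold apart were 18 lower in Lin- against primary and 10 lower in Lym+ against primary. Likewise, without the 3 rarest clusters, list medians of Lin- against primary were mature neutrophil 0.10, neutrophil precursor -0.53, granulocyte-monocyte progenitor 0.11, monocyte or macrophage -0.064, basophil, eosinophil or mast -1.31, secondary and tertiary granule -0.34 and MHC class II 0.063. Likewise, without the 3 rarest clusters, list medians of Lym+ against primary were mature neutrophil 0.33, neutrophil precursor -0.11, granulocyte-monocyte progenitor -0.075, monocyte or macrophage -0.049, MHC class II 0.56 and chemokine receptors and adhesion -0.083. Likewise, without the 3 rarest clusters, list medians of Lym+ against Lin- were MHC class II 0.56. Again without the 3 rarest clusters, log2 ratios of Lym+ against primary were Camp 0.41, BC100530 0.020 and S100a8 0.26. Again without the 3 rarest clusters, log2 ratios of Lym+ against Lin- were H2-Ab1 -0.14 and Cd79b 0.015. In cells thinned to 500 UMIs, list medians of Lin- against primary were mature neutrophil -0.94, neutrophil precursor -1.33, secondary and tertiary granule -0.71, S phase 0.29 and immediate early and heat shock -1.34. Likewise, in cells thinned to 500 UMIs, list medians of Lym+ against Lin- were neutrophil precursor 0.092, Hoxa9/Meis1 program 0.076, MHC class II 2.43, S phase -0.68 and G2 and M phase -0.80. Likewise, in cells thinned to 500 UMIs, list medians of Lym+ against primary were MHC class II 2.67 and chemokine receptors and adhesion -0.046.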

Other observations

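The tests of explanations in this part, and the choice of the Y-linked genes and of the single cell, were made after the results were seen. The single Lym+ cell with 894 Ighm UMIs belonged to cluster 5, had 4890 UMIs in all, of which 18.3% were Ighm, and also held 2 Igkc, 1 Jchain and 5 Mzb1 UMIs. Glycolysis and hypoxia, oxidative phosphorylation and B-lineage transcription factor medians lay inside the range of random lists in the 3 comparisons. The chemokine receptor and adhesion median was 0.06 in Lin- against primary, 0.13 in Lym+ against primary and 0.04 in Lym+ against Lin-, and the median of 0.13 was -0.083 without the 3 rarest clusters and -0.046 in cells thinned to 500 UMIs. The checkpoint and antigen presentation median was 0.20 in Lin- against primary and -0.31 in Lym+ against Lin-, with B2m at 927.1, 1194 and 978.6 CPM in the primary, Lin- and Lym+ recipients. The monocyte or macrophage median was 0.12 in both comparisons with the primary, and 2 of 11 members were at least 1.5-fold lower in the Lin- recipient; without the 3 rarest clusters these medians were -0.064 and -0.049, and in cells thinned to 500 UMIs they were 0.011 and 0.0050. The Hoxa9/Meis1 program median was -0.19 in Lin- against primary, 0.032 in Lym+ against primary, with 3 of 9 members higher and 1 lower, and 0.26 in Lym+ against Lin-; in cells thinned to 500 UMIs the last 2 were -0.098 and 0.076, and in cells with at least 1000 genes -0.047 and 0.22. Few markers of other cell types with deposited values reached a mean of 10 CPM over the 3 mice. These were 2 of 6 erythroid genes, 2 of 9 mature B genes, 1 of 6 plasma cell genes and 1 of 11 T or NK genes. Of the stromal or endothelial genes it was 1 of 1, and of the megakaryocyte or platelet genes 0 of 4. The full lists hold 15, 11, 7, 14, 9 and 8 genes in that order. Their other genes were absent from the deposited expression values, so their levels are not known.

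Transcripts of the Y chromosome differed among the mice, although both secondary recipients received cells of the primary. Eif2s3y (chromosome Y, 1010543 to 1028847), Ddx3y, Uty and Kdm5d summed to 102.2 CPM (94.6 to 110.3) in the primary, 39.4 CPM (35.6 to 43.4) in the Lin- and 3.44 CPM (2.18 to 5.16) in the Lym+ recipient. At 500 UMIs per cell Eif2s3y was in 0.0339% of Lym+ and 2.23% of primary cells, which argues against depth, and in 8 of 8 clusters with at least 50 cells of each mouse the Lym+ upper bound lay over 2-fold below the primary lower bound, which argues against composition as the whole cause, although in cluster 8, with 33 Lym+ cells and 4 of the 23 Lym+ UMIs, the values were 32.8 CPM (8.94 to 84) and 102.8 CPM (82.2 to 127). Female cells would bring Xist, whose upper bound in the Lym+ recipient was 2.16 CPM, and primary cells wrongly assigned at random to the Lin- recipient would have to be at least 32.3% of its cells and bring their other transcripts, while 13 of 2453 genes at 50 CPM or more in the primary, such as Cebpe and Fos, had Lin- upper bounds below the level this needs. A hypothesis that stays open is that the Lin- recipient may hold a mixture of cells with and without Y-linked transcripts: 43 of its cells (31.1 to 57.9) had UMIs of at least 2 of the 4 genes where independent detection gives 16.5, against 62 primary cells (47.5 to 79.5) where it gives 52.6, and the sex of donor and recipients was not used here.

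Immediate early genes were lower in the Lin- recipient than in both other mice. Composition as the cause is argued against by list medians below the random range in 8 of 8 clusters, and depth by a median of -1.34 at 500 UMIs per cell. These genes also respond to handling of tissue, and with 1 mouse per group a difference in handling before pooling cannot be told apart from a difference between the mice.

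MHC class II genes were higher in the Lym+ recipient than in both other mice, mostly through cluster 9. Against the primary, a larger cluster 9 alone may leave a remainder. The 4 members that reached 10 CPM in at least 1 mouse outside it were all higher, with a median log2 ratio of 0.34. The random range was -0.32 to 0.12. Cd74 reached 10 CPM there only in the Lym+ recipient, at 13.3 CPM against 6.90 CPM, so its own rise placed it among the 4. The others, H2-Ab1, H2-DMa and H2-DMb1, had log2 ratios of 0.35, 0.29 and 0.34, and no random range was drawn without Cd74. Against the Lin- recipient the median of these 4 was 0.18 (random range -0.26 to 0.17), with Cd74 at 13.3 CPM against 4.61 CPM. H2-Ab1 was lower at 31.2 CPM against 34.4 CPM, a log2 ratio of -0.14, and H2-DMa and H2-DMb1 had 0.066 and 0.30. Without Cd74 the middle value, 0.066, lies inside the range drawn for the 4. The list median was lower in 3 of 8 clusters, so it stays open there whether cluster 9 accounts for the whole difference. Free RNA from cluster 9 may add to these values and was not tested. Whether cluster 9 lies outside the leukaemia cannot be told apart here: at 500 UMIs per cell Hoxa9 was in 0.625% (0.0158 to 3.43) of its cells and 1.37% of the others, too few counts to decide.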
